A study of Mus musculus with 2 samples.

How the data were processed

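Mouse Vγ4 γδ T cells, sorted from the thymus and from the peripheral lymph nodes of C57BL/6 mice 8 to 12 weeks old, were profiled by 5′ single-cell V(D)J sequencing on the 10x Genomics platform, per the labels. γδ T cells carry a receptor made of a γ chain (locus TRG) and a δ chain (locus TRD), and Vγ4 is the V region of the γ chain that the sort selected. GEO lists 1 sample per organ, and 3 contig tables were deposited for each sample, 6 in all.

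Reads were processed with Cell Ranger 3.1 and the genome build mm10, per the submitters' processing notes. The V(D)J reference and the primers used for enrichment are not given in the sources used here. Each deposited table is a list of assembled contigs with the raw read counts and raw UMI counts per contig, per the file headers, with no normalization. The other deposited columns are contig length and text annotation of the V, D, J and C segments, the productive flag and the CDR3, the junction that forms most of the antigen contact. In all 6 tables every contig carried the cell and high-confidence flags, so the tables had been filtered on both before they were deposited by the authors.

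The 3 tables of an organ were found to be repeat runs of 1 set of barcoded cells. Any 2 runs shared between 96.2% and 97.6% of the barcodes of the smaller one in lymph node and between 80.5% and 85.4% in thymus. The leading TRD CDR3 was the same nucleotide sequence in 97.5% to 97.9% of shared lymph node cells and in 92.4% to 93.0% of shared thymus cells. Across organs 61 barcodes coincided, and none of the 42 of these with a TRD chain in both organs had the same CDR3. The runs were therefore merged by barcode, as planned for this case, and are given as a technical range, not as replicates. With 1 sample per organ no test between organs was possible, and no p-value is given. Shares carry exact (Clopper-Pearson) 95% binomial intervals and ratios of shares carry 95% log-normal intervals. Where a count was 0, the limit given is 3 counts over the group's total, which is lower than the exact 95% upper bound. Intervals and limits cover counting error only and leave out the spread between animals, sorts and libraries. They treat cells as independent, so they are too narrow where cells are copies of 1 clone.

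A TRD contig was a productive contig with a TRDJ segment that Cell Ranger had assigned to TRD, or to several loci because its V segment belongs to the overlapping TRA locus. A cell was a barcode with at least 1 such contig, and the chain with most UMIs in any run was taken as its leading chain. V segments that differ only by D or N in the name, which are near-identical copies, were counted together, because reads can be assigned to either copy. The TRAV15-DV6 family was pooled further, over both of its gene numbers, DV6-1 and DV6-2. A clonotype was a V segment with 1 nucleotide CDR3. Diversity was compared after thinning thymus to the 3977 cells of lymph node in 1000 random draws. In other settings it was thinned to the smaller organ or run of that setting, unless said otherwise. No doublet caller was run, since the tables hold no expression matrix, and barcodes with over 1 productive TRD chain were left out as an alternative.

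No contig in the tables had TRGV4 as its V segment, although the sort was for Vγ4. All productive TRG contigs, 809 over the 6 tables, carried TRGV2. The planned restriction to cells with a productive TRGV4 chain could not be applied, and the wider population named for this case beforehand, every barcode with a productive TRD chain, became the population used throughout. The identity of the sorted γ chain was thus not checked by these tables. Pairing with TRGV4, clonotypes by paired chains and the count of added nucleotides, which needs a genome sequence, were not analysed here.

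Reads numbered 1410182, 1145865 and 1139848 in the lymph node runs and 936105, 725663 and 714687 in the thymus runs. Lymph node had 821 reads per barcode and thymus 205, so thymus was sequenced less deeply per barcode. A productive TRD chain was found in 88.3% of 4503 lymph node barcodes (95% interval 87.3 to 89.2) and in 72.8% of 11606 thymus barcodes (72.0 to 73.6). The median leading chain rested on 13 UMIs in lymph node and 14 in thymus.

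Before the data were examined, the following rule was set for the items named in the text. V segments with at least 2% of cells in either organ, the 5 most frequent TRD CDR3s of each organ, the 3 most frequent TRG CDR3s, every CDR3 with at least 1% of cells and a list of fixed sequences are reported. An item is called higher in an organ only where the 95% intervals do not overlap, the ratio is at least 1.5, and every run of that organ lies above every run of the other. The alternatives were the contig flags, a minimum of 2 UMIs, barcodes with 1 chain only, clonotypes counted once, the mean of runs, runs left unmerged, each run left out in turn, and other clonotype and diversity definitions. Chains in 2 or more runs, chains with 20 UMIs or more, every contig with a δ V segment, the TRAV15-DV6 family split by gene number and cells without the germline CDR3 were added after seeing the data. Coordinates are those of GRCm38.p6, which is mm10, in the NCBI RefSeq gene table, where all 61 V segment names of the contig tables were found.

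Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The merging and ratio steps were tested on 100 simulated pairs of organs with the real cell numbers, 3977 and 8454. A simulated thymus to lymph node ratio of 0.03 was recovered as 0.0303 on average, with 94% of intervals covering it, and a ratio of 2 was recovered as 1.99, with 98% covering. Within an organ, all simulated V segments had the same chance of being read in a run and the same distribution of UMIs. The simulation thus checked the code and could not show whether merging shifts the shares of V segments in the real data.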

Results

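Single-cell V(D)J sequencing of sorted Vγ4 γδ T cells gave 3977 lymph node cells and 8454 thymus cells with a productive TRD chain, from 1 sample of each organ. The series concerns γδ T cells that develop in the adult thymus and whether they reach the periphery, and the comparison asked how the δ chains of thymic and peripheral Vγ4 cells differ. Because each organ had 1 sample, whose 3 tables are repeat runs of the same cells, every difference below compares these samples. No difference has a replicate check, and the 95% intervals cover counting error only.

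The δ chain V segments were distributed differently in the thymus and the lymph nodes. In lymph node, TRDV5 (Vδ5) and TRAV13-4-DV7 (Vδ7) made up most cells, at 38.8% (95% interval 37.3 to 40.4) and 36.4% (34.9 to 37.9). In thymus, TRDV2-2 (Vδ4) was the most frequent segment, at 44.7% (43.6 to 45.7). Of the 31 V segments or families seen, 6 reached 2% of cells in either organ, of which 1 was higher in lymph node, 3 were higher in thymus and 2 did not meet the rule.

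TRAV13-4-DV7, at chromosome 14, 53757410 to 53757921 on GRCm38.p6, was 3.08 times as frequent in lymph node as in thymus (2.87 to 3.31), where 11.8% of cells carried it (11.1 to 12.5). Its share in single runs was 38.1% to 38.8% in lymph node and 12.9% to 14.1% in thymus, above the merged share in both organs. TRDV2-2, at chromosome 14, 53960993 to 53961602, was 2.87 times as frequent in thymus (2.66 to 3.09) and reached 15.6% in lymph node (14.5 to 16.8). The TRAV15-DV6 family (Vδ6) made up 5.16% of thymus cells (4.70 to 5.65) and 3.29% of lymph node cells (2.76 to 3.90), a ratio of 1.57 (1.29 to 1.90). This ratio was 2.37 when barcodes with over 1 productive TRD chain were left out, but 1.30 with each clonotype counted once and 1.42 without the germline TRDV5 CDR3, both under the size required for a call. Its annotated copies TRAV15-2-DV6-2 and TRAV15D-2-DV6D-2 were higher in thymus on their own, with ratios of 1.64 and 1.73. TRAV15-1-DV6-1, with 13 lymph node and 18 thymus cells, had a ratio of 0.651 (0.319 to 1.33). With D and N copies pooled, DV6-2 was higher in thymus by 1.68 (1.35 to 2.10), while DV6-1, with 34 lymph node and 89 thymus cells, had a ratio of 1.23 (0.831 to 1.82) and did not meet the rule. TRDV1, at chromosome 14, 53881612 to 53882217, was held by 2.27% of thymus cells and 0.654% of lymph node cells, a ratio of 3.47 (2.31 to 5.22), and of 6.38 without barcodes with over 1 productive chain. The segments outside TRDV5, TRAV13-4-DV7, TRAV15-DV6 and TRDV2-2 together, with TRDV1 among them, made up 9.78% of thymus cells (9.16 to 10.4) and 5.91% of lymph node cells (5.20 to 6.69). Their ratio, 1.66 as reported, was 1.36 with each clonotype counted once, 1.36 among chains with 20 UMIs or more and 1.498 without the germline CDR3, under the size required.

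TRDV5, at chromosome 14, 54148662 to 54149201, was 1.36 times as frequent in lymph node as in thymus (1.29 to 1.43), below the ratio required for a call. Its thymus share was 28.6% (27.6 to 29.6). The merged TRDV5 shares lie above those of the single runs, 35.3% to 36.7% in lymph node and 24.7% to 27.7% in thymus. A productive TRD chain was read in all 3 runs in 78.7% of lymph node cells and 42.3% of thymus cells. Among chains with 20 UMIs or more the ratio turned, to 1.20 thymus over lymph node. TRAV13-2 was held by 2.67% of lymph node cells (2.19 to 3.21) and 2.16% of thymus cells (1.87 to 2.498), and did not differ beyond counting error.

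**Figure D1:**
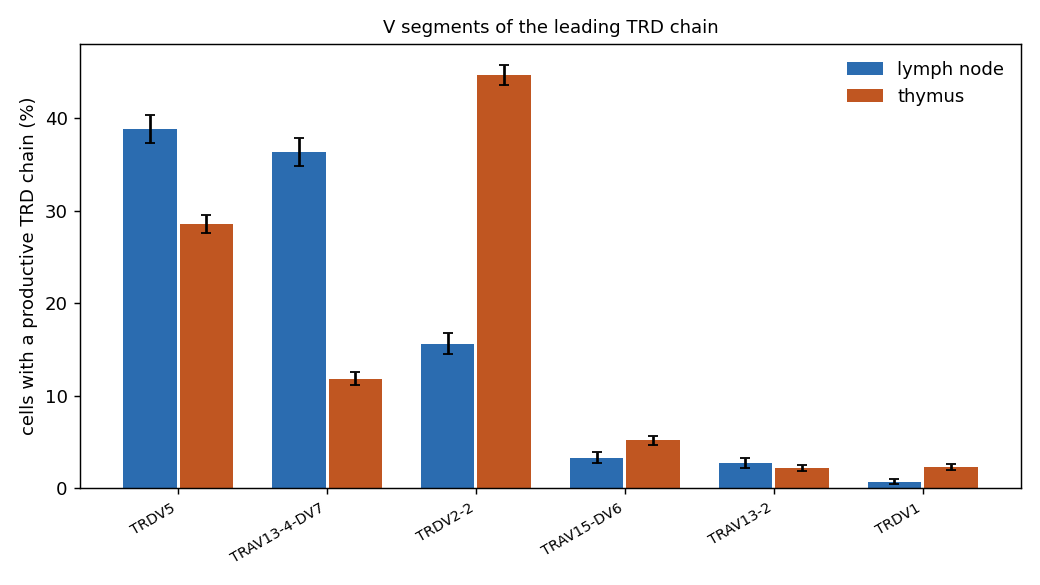
Percent of cells with a productive TRD chain (vertical axis) whose leading chain used each V segment, for the 3977 lymph node and 8454 thymus cells. Bars are the shares of the 1 sample per organ and error bars are exact 95% binomial intervals, with TRAV13-4-DV7 at 36.4% in lymph node against 11.8% in thymus and TRDV2-2 at 15.6% against 44.7%.

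TRDJ1 was the joining segment of 99.7% of cells in both organs. TRDJ2 was used by 11 lymph node and 23 thymus cells, 0.277% and 0.272%, a thymus to lymph node ratio of 0.984 (0.480 to 2.02). Among chains with 20 UMIs or more it was used by 1 of 846 lymph node and 12 of 2355 thymus cells, a ratio of 4.31 with an interval of 0.561 to 33.1. A TRDD2 segment was annotated in 69.1% of thymus and 51.6% of lymph node chains, a ratio of 1.34 that is under the required size. This ratio was 1.59 with each clonotype counted once, and among chains with 20 UMIs or more 1.68, both above that size. TRDD1 was annotated in 2.38% of thymus and 1.36% of lymph node chains, higher in thymus by a ratio of 1.75 (1.30 to 2.36). No D segment was annotated in 47.0% of lymph node chains and 28.5% of thymus chains, higher in lymph node by 1.65 (1.57 to 1.73). The D annotation is the caller's and can be missed in a chain that holds a D segment. The residues GGI, EGY and RRD, which TRDD2 can encode, were found in 46.4%, 10.2% and 18.2% of lymph node cells. In thymus they were found in 28.4%, 18.6% and 18.6% of cells. GGI was thus more frequent in the organ with fewer annotated TRDD2 segments. The annotated shares therefore cannot be read as shares of chains that hold or lack a D segment.

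The most frequent δ chain of the lymph node was the TRDV5 chain with the CDR3 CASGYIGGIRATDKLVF, known as the public germline-encoded junction of Vγ4 Vδ5 cells. It was carried by 389 lymph node cells, 9.78% (8.88 to 10.7), and by 25 thymus cells, 0.296% (0.191 to 0.436). The lymph node share was 33.1 times the thymus share (22.1 to 49.5). Within TRDV5 cells it made up 25.2% in lymph node (23.0 to 27.4) and 1.03% in thymus (0.6705 to 1.52). TRDV5 cells with any other CDR3 made up 29.0% of lymph node cells (27.6 to 30.5) and 28.3% of thymus cells (27.3 to 29.3). The share of the germline CDR3 in single runs was 8.68% to 8.95% in lymph node, below the merged share, and 0.141% to 0.341% in thymus. Without thymus run 1 its thymus to lymph node ratio was 0.0198 against 0.0302 with all runs. With each clonotype counted once it was 0.0861, and that of all chains ending in IGGIRATDKLVF was 0.445.

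In lymph node, 367 of the 389 cells, 94.3%, had the nucleotide sequence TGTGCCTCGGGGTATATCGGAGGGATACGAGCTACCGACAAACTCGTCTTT, which 20 of the 25 thymus cells also had. The lymph node cells held 9 distinct nucleotide sequences for this CDR3 and the thymus cells 2. Chains of any V segment that ended in IGGIRATDKLVF made up 20.9% of lymph node cells (19.7 to 22.2) and 4.99% of thymus cells (4.54 to 5.48), higher in lymph node by 4.20 (3.76 to 4.69). With the germline CDR3 left out, the shares were 11.2% and 4.70%, a ratio of 2.38 (2.09 to 2.71). The ending was higher in lymph node within TRDV5 cells (38.7% against 6.54%), TRAV13-4-DV7 cells (10.6% against 4.81%) and TRDV2-2 cells (7.58% against 4.21%). Within TRAV15-DV6 cells it was found in 9 of 131 lymph node and 25 of 436 thymus cells and did not meet the rule.

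Further frequent lymph node CDR3s had the same ending or a closely related one. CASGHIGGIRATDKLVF, also on TRDV5, was held by 41 lymph node cells and 3 thymus cells, with a ratio of 29.1 (9.002 to 93.8). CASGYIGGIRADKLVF on TRDV5 was held by 34 lymph node cells and 1 thymus cell, a ratio of 72.3 with an interval of 9.90 to 528, and its thymus to lymph node ratio was 0.0138 with all runs and 0.0300 without thymus run 2. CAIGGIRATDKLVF, on TRAV13-4-DV7 or TRAV13-2, was held by 29 lymph node cells and 3 thymus cells, a ratio of 20.5 (6.26 to 67.4). With each clonotype counted once the thymus to lymph node ratio of each of these 3 CDR3s was 0.129, against 0.0344, 0.0138 and 0.0487 over cells. Among chains with 20 UMIs or more it was 0.0718, 0.180 and 0.120. These CDR3s led only 3, 1 and 3 thymus cells before that cutoff, so these ratios rest on very few cells. The TRDV2-2 chains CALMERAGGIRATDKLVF and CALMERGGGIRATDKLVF were higher in lymph node by 2.83 (1.61 to 4.98) and 3.72 (1.83 to 7.55), although TRDV2-2 itself was lower there. They were held by 28 and 21 lymph node cells and by 21 and 12 thymus cells.

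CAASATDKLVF, on TRAV14 segments, led 16 thymus cells, 0.189%, and 0 lymph node cells, which allows a share of up to 0.0754%. Counted in any TRD chain of a cell, leading or not, it was held by 18 thymus cells and 1 lymph node cell, a ratio of 8.47 with an interval of 1.13 to 63.4. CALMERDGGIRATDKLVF was held by 11 thymus and 3 lymph node cells and did not meet the rule. The fetal Vδ1 sequence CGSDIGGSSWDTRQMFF was found in 0 cells of either organ, which allows up to 0.0754% in lymph node and 0.0355% in thymus by the 3-count limit. The W(S)EGYEL motif of chains that bind the MHC class Ib molecules T10 and T22 was found in 1 cell of each organ.

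**Figure D2:**
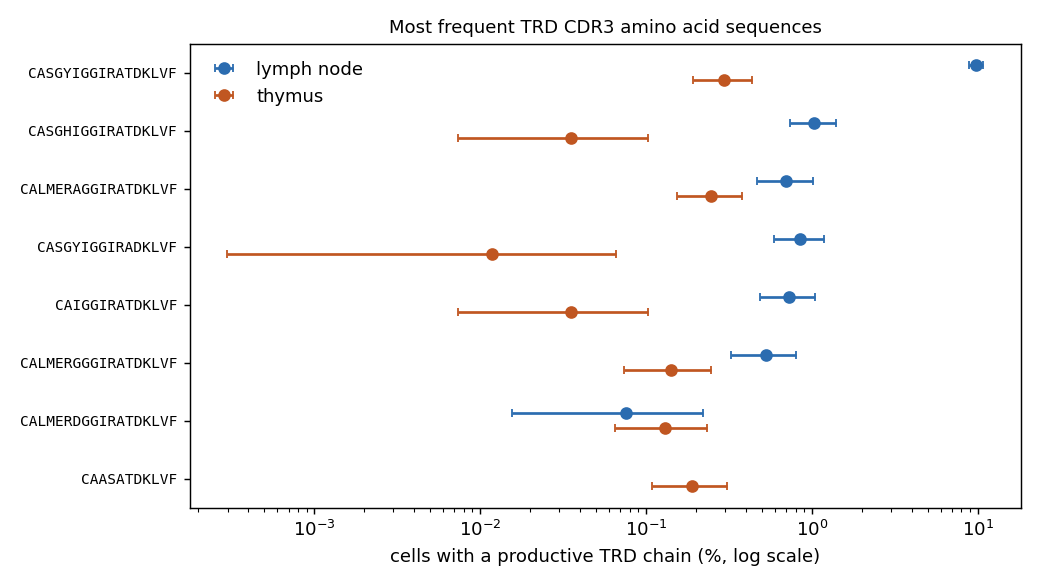
Percent of cells (horizontal axis, log scale) whose leading TRD chain had each CDR3 amino acid sequence, for the most frequent sequences of each organ. Points are the shares of the 1 sample per organ, lines are exact 95% binomial intervals, and a sequence with 0 cells in an organ has no point, with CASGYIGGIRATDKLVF at 9.78% in lymph node and 0.296% in thymus.

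TRD CDR3s were shorter in lymph node than in thymus. Their mean length over cells was 16.9 ± 2.61 amino acids (SD over 3977 cells) in lymph node and 17.9 ± 2.87 (SD over 8454 cells) in thymus, a difference of 1.02. The means of single runs were 16.8 in each lymph node run and 17.8 in each thymus run. With each clonotype counted once the difference was 0.975. Within V segments thymus CDR3s were longer by 0.595 in TRDV2-2, 0.532 in TRDV5 and 0.531 in TRAV13-4-DV7 cells. Over clonotypes these differences were 0.509, 0.243 and 0.416. In TRAV15-DV6 the difference was 0.214 over cells and over clonotypes, from 131 lymph node and 436 thymus cells with SDs of 2.71 and 2.79. Its single-run means were 17.97 to 18.33 in lymph node and 18.41 to 18.55 in thymus. With so few cells and this spread, no difference is called for TRAV15-DV6. A length of 17, that of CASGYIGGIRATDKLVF, was found in 26.3% of lymph node and 13.6% of thymus cells. Without this CDR3 the difference was 1.03. These differences have no replicate check.

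**Figure D3:**
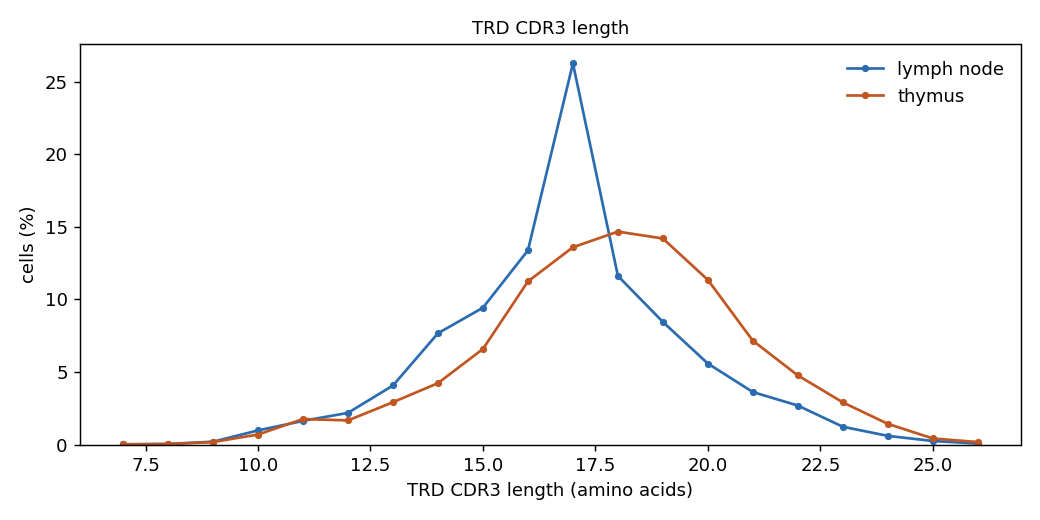
Percent of cells (vertical axis) at each TRD CDR3 length in amino acids (horizontal axis) in lymph node and thymus. Lines join the shares of the 1 sample per organ, which peak at 17 amino acids in lymph node (26.3%) and at 18 in thymus (14.7%).

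Lymph node δ chains recurred between cells far more often than thymus δ chains. In lymph node 24.3% of cells (23.0 to 25.7) had a TRD clonotype seen in at least 2 cells, against 3.18% in thymus thinned to the same 3977 cells (2.59 to 3.77 over the middle 95% of draws). The lymph node share was 7.66 times the thymus share, and 5.95 times without the germline CDR3. The effective number of clonotypes, the exponential of the Shannon entropy, was 1797 in lymph node and 3848 in thinned thymus, a ratio of 2.14. Without the germline CDR3, at 3588 cells each, these numbers were 2740 and 3498, a ratio of 1.28. The thymus to lymph node ratio of recurrent cells, 0.131 as reported, was 0.216 by amino acid CDR3, 0.206 unthinned, 0.0793 among chains with 20 UMIs or more and 0.654 with runs unmerged, which counts a cell up to 3 times. The effective number ratio was 1.37 with 20 UMIs or more, 3.26 with runs unmerged, 4.45 unthinned and 33.4 by the inverse Simpson index. Thinned settings used the smaller organ of that setting. The values with 20 UMIs or more are thus at 846 cells, not 3977. Both measures depend on the cell number, so these values are not comparable with the reported ones. In lymph node 9 clonotypes had 10 or more cells and the largest had 367, while in the 8454 thymus cells 2 had 10 or more and the largest had 20.

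Recurrent clonotypes were found in every main V segment of the lymph node except at low number in TRAV15-DV6. They made up 42.4% of lymph node TRDV5 cells (39.9 to 44.9), 19.5% of TRDV2-2 cells (16.5 to 22.9) and 12.3% of TRAV13-4-DV7 cells (10.7 to 14.1). Without the germline CDR3 the TRDV5 share was 23.2% (20.8 to 25.7). The corresponding shares of the unthinned thymus were 4.10%, 6.67% and 3.11%, and 3.09% for TRDV5 without the germline CDR3. Among TRAV15-DV6 cells 4 of 131 in lymph node and 6 of 436 in thymus were recurrent. Recurrence counts cells with the same δ junction, which can be copies of 1 clone or separate cells that made the same junction. These sources, and technical copies under several barcodes, were not told apart for recurrent clonotypes as a whole.

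Clonotypes found in both organs numbered 101, and they accounted for 17.3% of lymph node cells (16.2 to 18.5) and 2.58% of thymus cells (2.25 to 2.94). Without the germline CDR3 they accounted for 8.89% of lymph node cells (7.98 to 9.87) and 2.29% of thymus cells (1.98 to 2.63). Among chains with 20 UMIs or more, in 846 lymph node and 2355 thymus cells, they held 10.0% of lymph node cells. By amino acid CDR3 191 clonotypes were shared, holding 24.4% of lymph node and 4.89% of thymus cells. Shared clonotypes held 33.2% of lymph node TRDV5 cells, 18.7% of TRDV2-2 cells, 3.73% of TRAV13-4-DV7 cells and 1 of 131 TRAV15-DV6 cells. In thymus they held 3.35%, 3.02% and 1.70% of TRDV5, TRDV2-2 and TRAV13-4-DV7 cells and 1 of 436 TRAV15-DV6 cells. The thymus cells open to a match numbered 2417, 3776, 998 and 436, so these shares are not on an equal footing between segments. Without the germline CDR3 they held 12.3% of lymph node TRDV5 cells (10.5 to 14.3). The residues GGI of the TRDD2 segment were present in 93.6% of lymph node cells with a shared clonotype and 36.5% of those without. Leaving out germline cells, which hold GGI by definition, the shares were 86.2% and 36.1%. With each clonotype of either organ counted once, again without the germline CDR3, 71 of 99 shared clonotypes, 71.7%, and 28.9% of the others held GGI.

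At equal cell numbers, sharing within the lymph node exceeded sharing with the thymus. In 1000 random draws of 1988 cells, 21.0% of lymph node cells (19.7 to 22.4) had a clonotype of another 1988 lymph node cells, and 12.9% (11.2 to 14.4) had one of 1988 thymus cells. Without germline cells these shares were 12.6% and 3.99%. Among thymus cells 2.05% (1.46 to 2.62) had a clonotype of 1988 other thymus cells. The shares within an organ restate the recurrence within its 1 sample, so they are not separate evidence. The ranges are over random draws only.

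Productive γ chains were read in few cells and all used TRGV2, at chromosome 13, 19336573 to 19337026. A TRGV2 chain was found in 8.47% of lymph node cells (7.63 to 9.38) and 1.92% of thymus cells (1.63 to 2.23). Lymph node had 821 reads per barcode against 205, so this difference stands beside a difference in depth. TRGJ2 joined 97.6% of these chains in lymph node and 98.8% in thymus. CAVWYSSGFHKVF, the most frequent TRG CDR3 of the lymph node, was found in 16 of 337 lymph node and 5 of 162 thymus cells with both chains, a ratio of 0.650 (0.242 to 1.74) that did not differ beyond counting error. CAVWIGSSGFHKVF, the most frequent in thymus, was found in 14 lymph node and 6 thymus cells, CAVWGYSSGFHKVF in 13 and 5, and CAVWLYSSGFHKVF in 6 and 5. The TRGV4 junction of the form CSYG, any residue, YSSGFHKVF and the fetal junction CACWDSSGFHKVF were found in 0 cells, but the lack of TRGV4 annotation means that their absence cannot be read as a level.

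The TRGV2 chain was found in every main δ group of the lymph node, in 10.6% of TRDV5 cells (9.13 to 12.3), 8.87% of TRDV2-2 cells (6.75 to 11.4), 6.87% of TRAV15-DV6 cells (3.19 to 12.6) and 6.36% of TRAV13-4-DV7 cells (5.16 to 7.74). In thymus the same groups had 2.44%, 1.96%, 1.61% and 1.20%. Within TRDV5 cells the thymus to lymph node ratio was 0.230 with all runs and 0.130 without thymus run 1. Of the 16 lymph node cells with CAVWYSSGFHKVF, 10 carried TRAV13-4-DV7 and 2 carried TRDV5. Of the 5 thymus cells with it, 0 carried TRAV13-4-DV7 and 3 carried TRDV5. Among all 337 lymph node cells with both chains, 92 carried TRAV13-4-DV7 and 164 carried TRDV5. Among the 162 such thymus cells these numbers were 12 and 59. The counts are small and copies of 1 clone were not separated, so no difference in pairing between the organs can be read from them.

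Chains of other lymphocytes were searched as markers of other cell types. No barcode of either organ had a productive chain assigned to TRA, TRB or an immunoglobulin locus alone, which allows up to 0.0666% of lymph node and 0.0258% of thymus barcodes. A productive contig assigned to several loci without a TRDJ segment was found in 6 thymus barcodes, 0.0517% (0.0190 to 0.112), and 0 lymph node barcodes. In 5 of them TRDV5 or TRDV2-2 was joined to a TRBJ segment, and in 1 TRAV15D-2-DV6D-2 was joined to a TRGJ segment. The enrichment primers are not given in the sources used here, so αβ T cells and B cells could be present without such contigs. Over 1 productive TRD chain was found in 12.9% of lymph node cells (11.9 to 14.01) and 15.9% of thymus cells (15.2 to 16.7) after merging. In single runs this share was 10.7% to 12.0% in lymph node and 10.5% to 11.9% in thymus. After merging, 3 or more productive TRD chains were found in 18 lymph node cells, 0.453%, and 110 thymus cells, 1.30%, a ratio of 2.87 (1.75 to 4.73). For 2 or more chains the merged ratio was 1.23 (1.12 to 1.35), under the size required for a call. It was 2.11 among chains with 20 UMIs or more and 0.965 among chains seen in 2 or more runs, both also after merging. The share was thus close in both organs within runs, and the merged ratio depended on which chains were counted.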

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

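The tests of a single expanded clone, of incomplete contigs and of the germline CDR3 alone, and the settings of 20 UMIs or more and of chains seen in 2 or more runs, were chosen after the results were seen.

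Contigs outside the TRD measurement stood above the limit of a count of 0, in data that no comparison used. A TRBJ2-2 contig without a V segment was found in 23.6% of lymph node barcodes and 1.53% of thymus barcodes. An IGHG1 constant region contig without V or J was found in 22.1% of lymph node and 7.44% of thymus barcodes. A TRGJ1 contig without V was found in 14.6% of lymph node and 4.87% of thymus barcodes. A contig assigned to no locus was found in 52.0% of lymph node and 3.26% of thymus barcodes. Lymph node had 821 reads per barcode and thymus 205.

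The germline TRDV5 CDR3 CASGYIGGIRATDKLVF made up 9.78% of lymph node cells and 0.296% of thymus cells. Free RNA of an abundant sequence would give chains of few UMIs, but the leading germline chain had a median of 9 UMIs in lymph node against 11 for other TRDV5 chains, a ratio of 0.818 (resampling 0.818 to 1). Only leading chains were compared, and the germline chain led 389 of the 433 lymph node barcodes that held it. A comparison of medians cannot exclude free RNA in part of these cells. Expansion of 1 mature clone would leave 1 or 2 γ junctions, but the 55 germline cells with a productive TRGV2 chain held 39 distinct TRGV2 nucleotide junctions, the most frequent in 6 cells. A TRGV2 chain was read in those 55 of the 389 cells, so the other cells remain untested in this respect. A difference between the organs may account for the pattern as a hypothesis, and with 1 sample per organ the variation from sample to sample stays open.

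TRAV13-4-DV7 was more frequent and TRDV2-2 less frequent in lymph node, with TRAV13-4-DV7 at a thymus to lymph node ratio of 0.324. The ratio was 0.302 when every contig with a δ V segment counted, complete or not, and 0.286 when each clonotype counted once, which argues against incomplete contigs and against a few expanded clonotypes. Among chains with 20 UMIs or more the ratio was 0.405, still below 0.67. Chains of few UMIs were thus not the whole of the difference. This cutoff leaves the gap in reads per barcode in place, 821 in lymph node against 205 in thymus. It therefore cannot decide on read depth, which stays open. In chains with 20 UMIs or more TRAV13-4-DV7 rose to 51.4% in lymph node and 20.8% in thymus, so its share does move with UMI number in both organs. The organ may be the source as a hypothesis, and sample to sample variation stays open.

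The lymph node δ chains were less diverse, with 24.3% of cells in recurrent clonotypes against 3.18% in thinned thymus. Without germline cells the thymus to lymph node ratio of recurrent cells was 0.167, so the germline CDR3 was not the whole of the pattern. Leaving them out lowered the effective number ratio from 2.14 to 1.28 and the inverse Simpson ratio from 33.4 to 2.14. By these 2 measures the germline CDR3 made up much of the difference. Among chains seen in 2 or more runs, where false clonotypes that arise within a run would be fewer, the ratio of recurrent cells was 0.131. The runs read the same barcoded cells, so a false clonotype made before the runs would recur in them. This setting cannot decide on such clonotypes. The organ may be the source as a hypothesis, and sample to sample variation stays open.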

How the results depend on the processing

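No paired analysis was possible because each organ had 1 sample and no label links the animals. All values here are thymus to lymph node ratios unless said otherwise. Chains seen in 2 or more runs, 20 UMIs or more, germline cells left out, TRAV15-DV6 split by gene number and every contig with a δ V segment were chosen after seeing the data. Over 18 alternatives, leaving out of runs aside, 134 values stayed within the interval of the reported value, 52 left it and 5 reversed. Counting productive contigs whatever their other flags removed no contig, so it tested nothing and is not among them. TRAV13-4-DV7 stayed below 1 and TRDV2-2 above 1 in all alternatives run on them. Shares of TRGV4, clonotypes by paired chains and added nucleotides were not run. The cause of the shifts was not tested unless stated.

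With 2 UMIs or more the effective number ratio was 2.12. Without barcodes of over 1 productive chain TRAV13-4-DV7 was 0.299, TRAV15-DV6 2.37 and the effective number 2.22. With each clonotype counted once TRDV5 was 0.952, TRAV13-4-DV7 0.286, other segments 1.36, the germline CDR3 0.0861 and the IGGIRATDKLVF ending 0.445, as repeated cells no longer counted. As the mean of runs TRAV13-4-DV7 was 0.350, the effective number 1.95, shared lymph node cells 14.98% and barcodes with 2 or more TRD chains reversed to 0.978. With each run counted as separate cells, which counts a cell up to 3 times, the values were 0.349, 3.26 and 0.654 for TRAV13-4-DV7, the effective number and recurrent cells, and 0.982 for 2 or more chains. By amino acid CDR3 the effective number was 2.39, recurrent cells 0.216 and shared cells 24.4%. The inverse Simpson ratio was 33.4, and 2.14 without the germline CDR3, and unthinned the effective number was 4.45 and recurrent cells 0.206. TRAV15-1-DV6-1 alone reversed to 0.651, and with its D and N copies it was 1.23.

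Leaving out each run in turn gave 2.07 to 2.15 for the effective number, 0.696 to 0.757 for TRDV5 and 0.0198 to 0.0341 for the germline CDR3, the lowest without thymus run 1.

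In chains seen in 2 or more runs TRAV13-4-DV7 was 0.363, the effective number 1.93, shared cells 15.05% and 2 or more chains reversed to 0.965. With 20 UMIs or more, which left 846 lymph node and 2355 thymus cells, TRDV5 reversed to 1.20. There TRAV13-4-DV7 was 0.405, TRAV15-DV6 1.95, TRDV2-2 2.44, other segments 1.36, the germline CDR3 0.0189, the ending 0.334, the effective number 1.37, recurrent cells 0.0793, shared cells 10.0%, the length difference 1.27, 2 or more chains 2.11 and TRDJ2 4.31. Without germline cells TRDV5 was 0.882, TRAV13-4-DV7 0.294, TRDV2-2 2.59, the ending 0.381, the effective number 1.28, recurrent cells 0.167 and shared cells 8.89%. With every contig that had a δ V segment TRAV13-4-DV7 was 0.302.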

Other observations

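The reading frames of the TRDD2 segment and the close relatives of the germline CDR3 were examined after the CDR3 results were seen.

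The frame of TRDD2 that reads GGI was more frequent in lymph node, in 46.4% of cells (44.8 to 48.0) against 28.4% in thymus (27.5 to 29.4). The difference was smaller with each clonotype counted once, 35.6% against 27.4%. With each clonotype counted once and the germline CDR3 left out, TRDV5 clonotypes held GGI in 41.3% in lymph node and 26.9% in thymus. TRDV2-2 clonotypes held it in 37.0% and 28.7%. EGY, another frame, was found in 10.2% of lymph node and 18.6% of thymus cells, and in 11.4% and 20.2% of TRDV2-2 clonotypes. TRAV13-4-DV7 clonotypes differed in that RRD was found in 28.4% of lymph node and 19.6% of thymus clonotypes, while GGI was found in 31.6% and 29.0%. In TRDV5 clonotypes RRD went the other way, at 14.2% in lymph node and 19.1% in thymus. RRD was found in 18.2% of lymph node and 18.6% of thymus cells over all segments, and in 21.95% and 18.9% of clonotypes.

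TRDV5 chains that differ from the germline CDR3 by the residue before IGGIRATDKLVF, CASG then a residue other than Y, were held by 122 lymph node cells, 3.07% (2.55 to 3.65), and 25 thymus cells, 0.296% (0.191 to 0.436). The thymus to lymph node ratio was 0.0964 (0.0628 to 0.148) over cells and 0.141 over clonotypes, of which there were 44 in lymph node and 16 in thymus. A candidate explanation was sequencing or assembly errors of the abundant germline chain, which were predicted to leave the germline chain in the same cells. The germline chain was found in 0 of the 122 lymph node cells, 0%, and in 7 of 1033 other TRDV5 cells, 0.678%. An error that took the place of the germline contig would leave none there, so the count of 0 cannot exclude it. These variants may be junctions of their own, as a hypothesis from the same 1 sample per organ.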
